A study of Mus musculus with 6 samples.

How the data were processed

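Bulk RNA sequencing was done on macrophages sorted from atherosclerotic aortic plaques of Ldlr-deficient mice, a strain that develops plaques on a high fat diet. The mice had received bone marrow with loxP-flanked Vcam1 alleles, either without Cre (called WT here, 3 samples) or with 1 LysM-Cre allele (called Vcam1 KO here, 3 samples). LysM-Cre is a Cre recombinase gene placed in the lysozyme 2 locus, so that it is expressed in myeloid cells. The group and number of each sample come from its title, and the genotype label was the same within each group. The labels do not say whether each sample came from 1 mouse or from a pool, or that the samples were separate animals. The p-values therefore measure the spread between these samples, which may be technical.

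RNA was extracted from the sorted cells with a PicoPure kit and made into Illumina libraries, per the labels' protocols. The deposited values are RPKM, reads divided by gene length and by the sample's total, with 1 column per sample and 48709 gene symbols, per the file headers. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, its annotation and its handling of strand and of reads that map to several places are not given in the sources used here. Reads of paralogs, of overlapping genes and of antisense genes could therefore have been split in an unknown way, and genes that overlap others are marked as uncertain where their levels are given.

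Sequencing depth was worked out from the steps between low RPKM values, since each value of a gene is a whole number of reads divided by the gene's length and the sample's total. A search over whole totals below 80000000 reads in the first sample found 1 set that fitted the commonest ratios of values between samples. Multiples of that set, which lie above the limit, would fit as well. With these totals, 102541 of 102541 values above 0 came out as whole reads, within a relative tolerance of 1e-06. Each gene's length was taken from the same values, so that count is not an independent check. The totals were 41570951, 46195795 and 48827650 reads in WT 1 to 3, and 44609434, 49896364 and 51463189 in Vcam1 KO 1 to 3. Of 23343 genes above 0 with 1 annotated match, 16774 had a length equal to the exon length in GENCODE M21 or to a whole fraction of it, 71.9%. For 738 of these the values gave the reads only up to a whole factor, which was then set by the annotated length. For genes without such a match, the reads may be known only up to a whole factor. The recovered reads served to state depth, to give read numbers of single genes and 1 ratio of read rates, and for 1 alternative test. Read numbers cover counting error only, because duplicates of a molecule could not be told from separate molecules.

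Genes with an RPKM of at least 1 in at least 3 samples were kept, and 9799 were tested. The values were put on the log2(RPKM + 1) scale, which understates the change of low genes, and were not scaled further. Groups were compared over all 6 samples with limma 3.58.1 in R 4.3.3 (linear model with group as the only term, then empirical Bayes with an intensity trend). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The design had been written for counts and for normalized values, and the branch for normalized values applied. Log2 fold changes are Vcam1 KO minus WT, two-sided tests throughout unless stated. Single values were also compared by an exact permutation test, whose smallest possible p with 3 against 3 samples is 0.1. The level of a gene is given as mean RPKM ± SD.

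Before the data were examined, 38 gene lists (pathways and cell type markers) were fixed, and 34 with at least 3 tested members were tested with camera in limma, with its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. The same lists were tested with a correlation estimated from the data and with fry. Members were also adjusted over their list alone. That adjustment does not correct for the number of lists, and a gene can be in several lists. The rule for named genes was also fixed then. It takes Vcam1 and Lyz2, then up to 12 genes per direction past the threshold with a mean RPKM of at least 2 and no overlap between groups, leaving out predicted genes and pseudogenes. Open places were filled with the genes of smallest p under the same conditions, which are named as not passing. Of each list the rule takes up to 4 members with the smallest p, and of other cell types' markers up to 3 with the highest mean. Genes named outside that rule are said to be so.

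The gene test and the list test were tested on simulated data made from the 9799 genes of this comparison, with 200 genes changed in each of 10 runs. Of the changed genes, 16.6% were called at a 2-fold change, 71.0% at 4-fold, 92.2% at 8-fold and 96.4% at 16-fold, and 6.31% of the calls were unchanged genes. With 200 changed genes in a run the adjusted threshold is easier to pass than where few genes change. The shares called may therefore be too high for these data. A list moved by 1.5-fold was called in 20 of 20 runs, and 0 of 600 unmoved lists were called. Simulated genes varied independently, so those runs do not show how the list test behaves when the members of a list vary together.

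Alternatives covered the filter on low values, the pseudocount, quantile normalization, the replicate number as a block, leaving out each sample, both other list tests, and 4 settings added after the data were seen. Coordinates are from GENCODE M21 on mm10, matched by gene symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Outliers within a group were not tested, since groups of 3 are too small for the test used.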

Results

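Transcript levels were measured in macrophages sorted from aortic plaques of mice that carried WT or Vcam1 KO bone marrow, with 3 samples in each group. The comparison asks how loss of VCAM-1 in myeloid cells alters the transcripts of plaque macrophages. Total reads ranged from 41570951 to 48827650 in WT and from 44609434 to 51463189 in Vcam1 KO. Reads assigned to genes were 81.9, 73.3 and 79.2% of the total in WT 1 to 3, and 82.3, 82.4 and 83.6% in Vcam1 KO 1 to 3. That share was higher in every Vcam1 KO sample than in any WT sample (exact permutation test, p = 0.1, the smallest possible). The RPKM sums did not overlap either, at 366020 to 399269 in WT and 409496 to 448620 in Vcam1 KO. Effects of these measures and of genotype cannot be told apart. Between 15728 and 17966 genes had a value above 0 in a sample.

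Vcam1 transcripts were lower in each of the 3 Vcam1 KO samples than in any WT sample. Vcam1, which encodes the cell adhesion molecule VCAM-1, lies on chromosome 3 at 116109949 to 116129688 on the minus strand, and the antisense gene Gm43109 overlaps it. Its level was 23.5, 13.5 and 34.6 RPKM in WT 1 to 3, and 3.83, 0.051 and 7.04 RPKM in Vcam1 KO 1 to 3. The means were 23.9 ± 10.6 and 3.64 ± 3.50 RPKM (SD, n = 3 each), so the WT mean was 6.57 times the Vcam1 KO mean. Between 13 and 1850 reads per library remained in Vcam1 KO. The log2 fold change was -2.76 with a standard error of 0.65. With limma, the unadjusted p was 0.00185 and the adjusted p over all genes was 0.934. The exact permutation p of 0.1 is the smallest that 3 against 3 samples allow.

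Transcripts of both lysozyme genes on chromosome 10 differed between the groups in opposite directions. Lyz2, the lysozyme gene that carries Cre in the Vcam1 KO marrow (117277331 to 117282321), averaged 13561 ± 5870 RPKM in WT and 7086 ± 1174 RPKM in Vcam1 KO (SD, n = 3 each). Its log2 fold change of -0.86 (standard error 0.38) did not pass the adjusted threshold (limma, unadjusted p = 0.0456, adjusted p = 0.970). Lyz1, the adjacent lysozyme gene best known from Paneth cells of the intestine (117287797 to 117292868), rose from 12.2 ± 2.76 to 334 ± 93.9 RPKM, a ratio of means of 27.4. Its log2 fold change was 4.65 with a standard error of 0.27 (limma, adjusted p = 0.000134). All 3 Vcam1 KO samples lay above all 3 WT samples. Lyz1 and Lyz2 are close paralogs, and how reads that match both were counted is not known, so both levels are uncertain to that extent. Lyz1 was at 0.068, 0.0996 and 0.120% of the Lyz2 level in WT 1 to 3, and at 4.07, 4.69 and 5.19% in Vcam1 KO 1 to 3.

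In all, 3 of 9799 genes passed the adjusted threshold of 0.05, and besides Lyz1 these were Fcor (higher) and Apoc4 (lower). Fcor, which encodes a corepressor of a forkhead transcription factor (chromosome 8, 3671188 to 3672362), had 1 read in the 3 WT libraries together and 360 reads in the 3 Vcam1 KO libraries. The ratio of read rates was 337, with an exact 95% counting interval of 60.1 to 13343. Its level rose from 0.020 ± 0.035 to 6.19 ± 2.20 RPKM, a log2 fold change of 2.77 with a standard error of 0.31 (limma, adjusted p = 0.0256). Apoc4, an apolipoprotein gene of the Apoe cluster (chromosome 7, 19678083 to 19681479), fell from 20.3 ± 10.3 to 0.97 ± 0.85 RPKM, a log2 fold change of -3.44 with a standard error of 0.43 (limma, adjusted p = 0.0487). The gene Gm44805 overlaps Apoc4 and Apoc2 on the same strand, so the levels of Apoc4 and Apoc2 are uncertain to that extent, and Gm44805 itself was at 2.79 ± 3.18 and 2.86 ± 1.19 RPKM. The neighbouring Apoc2, named after its values were seen, averaged 30.6 ± 28.7 and 42.6 ± 44.8 RPKM (adjusted p = 0.989). Fcor and Apoc4 were no longer called when any 1 of the 6 libraries was left out, with adjusted p of 0.0620 to 0.177 and 0.0725 to 0.228, while their log2 fold changes stayed at 2.55 to 2.98 and -3.70 to -3.01. Lyz1 was called in each of those 6 fits, with adjusted p of 0.000310 to 0.00216, but not when genes at low values were also tested (adjusted p = 0.110).

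**Figure D1:**
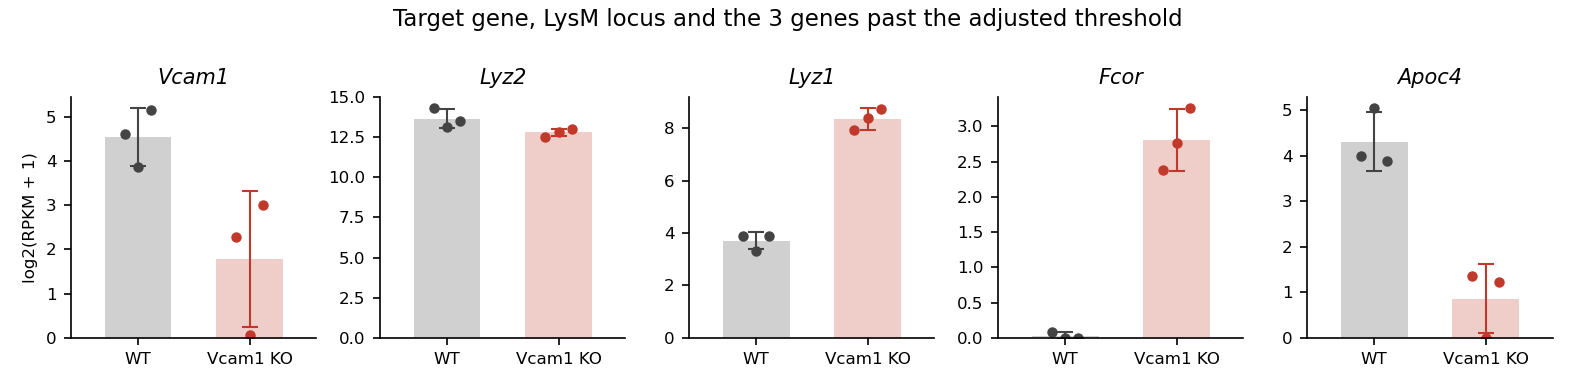
Levels of Vcam1, of the LysM locus gene Lyz2 and of the 3 called genes on the log2(RPKM + 1) scale. Points are the 3 libraries of each group, bars are means and error bars are 1 SD, and the groups do not overlap in any of the 5 panels.

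At an unadjusted p of 0.05, 413 genes were counted, against 490.0 that chance would give, with 242 higher and 171 lower in Vcam1 KO. That split of 58.6% higher became 26.4% when the RPKM values were scaled to equal sums, which shifted the median log2 fold change of all genes by -0.11, and 48.0% with voom on recovered reads. The groups did not overlap for 968 genes, 9.88%, where chance gives 10%.

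The next genes by p among those higher in Vcam1 KO included monocyte chemoattractants and matrix proteins, and none of them passed the adjusted threshold. Ccl12 averaged 842 ± 369 RPKM in WT and 2204 ± 498 RPKM in Vcam1 KO, and Ccl7 averaged 536 ± 229 and 1222 ± 117 RPKM. Both encode chemokines that attract monocytes. Spp1, which encodes osteopontin, averaged 63.0 ± 9.81 and 249 ± 170 RPKM, and Fn1, which encodes fibronectin, 4.99 ± 5.02 and 18.3 ± 3.0 RPKM. Spp1 was at 444 RPKM in Vcam1 KO 3 and at 129 and 174 RPKM in Vcam1 KO 1 and 2, and its log2 fold change was 1.25 without Vcam1 KO 3. Their log2 fold changes were 1.45 for Ccl12, 1.28 for Ccl7, 1.77 for Spp1 and 1.98 for Fn1, with standard errors of 0.34, 0.33, 0.40 and 0.48 (limma, adjusted p of 0.934 to 0.970). Without WT 2, which had the highest Fn1 of the WT libraries at 10.8 RPKM, Fn1 passed the threshold (adjusted p = 0.0384). Csad, an enzyme of taurine synthesis, averaged 2.08 ± 0.89 and 6.92 ± 0.76 RPKM (adjusted p = 0.785). Ms4a4c averaged 47.3 ± 17.4 and 111 ± 17.2 RPKM. The other 4 genes named in this direction were Prelid2 (3.56 ± 2.11 and 12.5 ± 0.18 RPKM), Apol9b (1.04 ± 0.38 and 3.90 ± 1.08 RPKM), the GDP-fucose transporter gene Slc35c1 (2.13 ± 0.69 and 5.66 ± 1.26 RPKM) and Grsf1 (1.77 ± 0.61 and 5.30 ± 1.6 RPKM), which encodes an RNA-binding protein of mitochondria. Their adjusted p and that of Ms4a4c lay between 0.934 and 0.970.

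Among genes lower in Vcam1 KO, Itgb7 and Nuak2 came next after Apoc4, both with an adjusted p of 0.514. Itgb7, a beta chain of integrins that bind VCAM-1 and the mucosal addressin (chromosome 15, 102215995 to 102231944), averaged 13.3 ± 5.14 RPKM in WT and 2.97 ± 1.25 RPKM in Vcam1 KO, a log2 fold change of -1.84 with a standard error of 0.33. Nuak2, a kinase of the AMPK family, averaged 22.8 ± 4.85 and 7.75 ± 1.61 RPKM, a log2 fold change of -1.44 with a standard error of 0.25. Receptor genes were also in this group. Cd244, a receptor of the SLAM family, averaged 7.98 ± 1.09 and 3.22 ± 0.46 RPKM, the prostaglandin receptor gene Ptger2 averaged 5.02 ± 2.34 and 0.94 ± 0.25 RPKM, and Il15ra averaged 7.20 ± 0.42 and 3.35 ± 0.23 RPKM. Tnfaip2, a target of tumour necrosis factor, averaged 7.59 ± 2.52 and 2.43 ± 1.76 RPKM. The other 4 were E2f6 (4.88 ± 0.28 and 1.96 ± 0.48 RPKM), Aldh18a1 (4.30 ± 1.66 and 1.33 ± 0.45 RPKM), Serpina3g (19.9 ± 12 and 6.56 ± 2.15 RPKM) and Fars2 (11.9 ± 1.44 and 6.44 ± 0.45 RPKM). The adjusted p of these 4, of Tnfaip2 and of the receptor genes lay between 0.934 and 0.970.

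**Figure D2:**
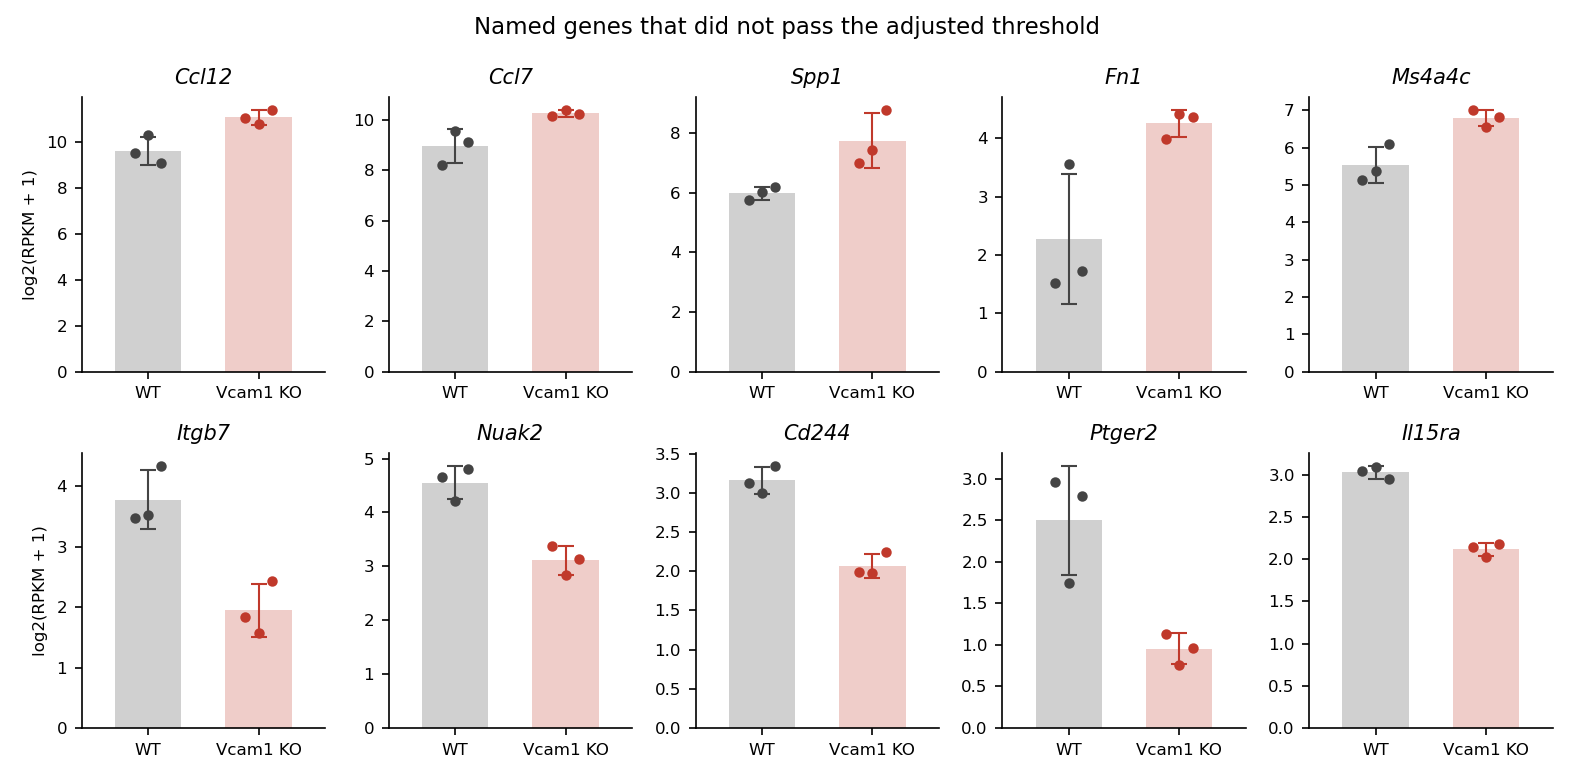
Levels of 10 named genes that did not pass the adjusted threshold, on the log2(RPKM + 1) scale. Points are libraries (3 per group), bars are means and error bars are 1 SD. Ccl12, Ccl7, Spp1, Fn1 and Ms4a4c lay higher in Vcam1 KO and the other 5 lower, with adjusted p of 0.514 to 0.970.

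Of the 34 gene lists tested, 7 were called with the preset correlation, 6 higher and 1 lower in Vcam1 KO, and 0 with a correlation estimated from the data or by fry. No member of the 7 called lists passed the threshold over all genes.

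Interferon response genes as a list were called higher in Vcam1 KO (camera, adjusted p = 8.3e-09). The log2 fold change was positive for 34 of 38 members, with a median of 0.57. Over all genes 0 members were called, and adjusted over the list alone 1 was higher, Ms4a4c, with a log2 fold change of 1.26 and a standard error of 0.27. Ifit3b averaged 14.1 ± 18.0 RPKM in WT and 28.8 ± 6.23 RPKM in Vcam1 KO, and the nucleic acid sensor gene Zbp1 averaged 11.6 ± 5.91 and 21.6 ± 6.83 RPKM. Ifit3b was at 34.8 RPKM in WT 3 and at 3.91 and 3.42 RPKM in WT 1 and 2, and it passed the threshold over all genes when WT 3 was left out. With an estimated correlation the adjusted p was 0.711. The list level, the mean of its members centred over the 6 libraries, was lowest in WT 1 at -1.02 and was 0.43 in WT 3, above the 0.12 and 0.02 of Vcam1 KO 2 and 3. Without WT 1 the call ended (adjusted p = 0.164).

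Cytosolic ribosomal protein genes and oxidative phosphorylation genes were called higher in Vcam1 KO, with adjusted p of 3.4e-07 and 1.9e-06 by camera. All 48 ribosomal protein genes had a positive log2 fold change, with a median of 0.30, and so had 42 of 44 oxidative phosphorylation genes, with a median of 0.29. No member was called over all genes or adjusted over the list alone. Rpl34 averaged 70.2 ± 21.1 and 101 ± 27.6 RPKM, and Ndufs4, a subunit of respiratory complex I, averaged 25.6 ± 5.09 and 39.7 ± 13.1 RPKM. With an estimated correlation the adjusted p was 0.744 and 0.711. Vcam1 KO 3 had the highest level of both lists, 0.64 and 0.47, and WT 2 the lowest, -0.49 and -0.43. The share of reads assigned to genes was also highest in Vcam1 KO 3 (83.6%) and lowest in WT 2 (73.3%), and WT 2 had the highest mitochondrial share of gene reads (8.70%). Without Vcam1 KO 3 the ribosomal protein list was not called (camera, adjusted p = 0.280), while oxidative phosphorylation still was (adjusted p = 0.0464). Without both WT 2 and Vcam1 KO 3 both lists turned negative (adjusted p = 0.0775 and 0.835).

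The list of immediate early and heat shock genes that tissue dissociation induces was called lower in Vcam1 KO (camera, adjusted p = 0.000289). The log2 fold change was negative for 19 of 22 members, with a median of -0.35. Hspa1b averaged 362 ± 134 and 184 ± 121 RPKM, Btg2 142 ± 26.1 and 89.2 ± 40.3 RPKM, and Jun 123 ± 12.6 and 76.2 ± 43.4 RPKM. With an estimated correlation the adjusted p was 0.711. Vcam1 KO 1 had the highest list level of the 6 libraries, 0.49, and Vcam1 KO 3 the lowest, -0.70, without which the call ended (adjusted p = 0.247). The unfolded protein response list was called higher (adjusted p = 0.0302, 14 of 17 members positive, median 0.31), with Creld2 at 31.3 ± 8.09 and 59.4 ± 30.3 RPKM. Its adjusted p was 0.774 with an estimated correlation, the call ended without WT 1 or WT 2 (adjusted p = 0.169 and 0.108), and the list turned negative without Vcam1 KO 1 (adjusted p = 0.734). The list level was 0.66 in Vcam1 KO 1 and -0.34 to 0.07 in the other 5 libraries. Vcam1 KO 1 also had the highest levels of the antibody genes Igkc (951 RPKM) and Jchain (37.1 RPKM, named after its values were seen). Mzb1 of the same B cell and plasma cell list, also named after its values were seen, went another way. It was at 0.77 RPKM in Vcam1 KO 1 and at 33.3 RPKM in Vcam1 KO 3. The gene SPATA24 overlaps Mzb1 on the same strand, so the Mzb1 level is uncertain to that extent.

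Lists of B cell and of dendritic cell markers were called higher in Vcam1 KO, with large differences between libraries of 1 group. Of the B cell and plasma cell list 5 of 14 genes were tested, all 5 with a positive log2 fold change (adjusted p = 0.0182, and 0.711 with an estimated correlation). Adjusted over the list alone 1 was higher, Cd79b, at 12.8 ± 4.79 and 32.8 ± 13.1 RPKM. Igkc, an antibody light chain gene, was at 0, 97.3 and 5.62 RPKM in WT 1 to 3, and at 951, 12.5 and 125 RPKM in Vcam1 KO 1 to 3. Ighm and Blnk of the same list were at 132 to 241 and 36.2 to 42.9 RPKM over all 6 libraries. In WT 1, where Igkc was at 0, they were at 132 and 39.8 RPKM, so both were present where Igkc was not seen. Of the dendritic cell list, 7 of 9 tested members were positive (adjusted p = 0.0201, and 0.711 with an estimated correlation). Cd209a was higher when adjusted over the list alone and was at 0, 6.28 and 1.32 RPKM in WT, and at 4.67, 138 and 45.7 RPKM in Vcam1 KO. Bst2 and Ifi205 of that list also belong to the interferon list. The B cell call ended without WT 1 or WT 3 (adjusted p = 0.169 and 0.0624), and the dendritic cell call without WT 1 or Vcam1 KO 1 (0.421 and 0.0627).

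**Figure D3:**
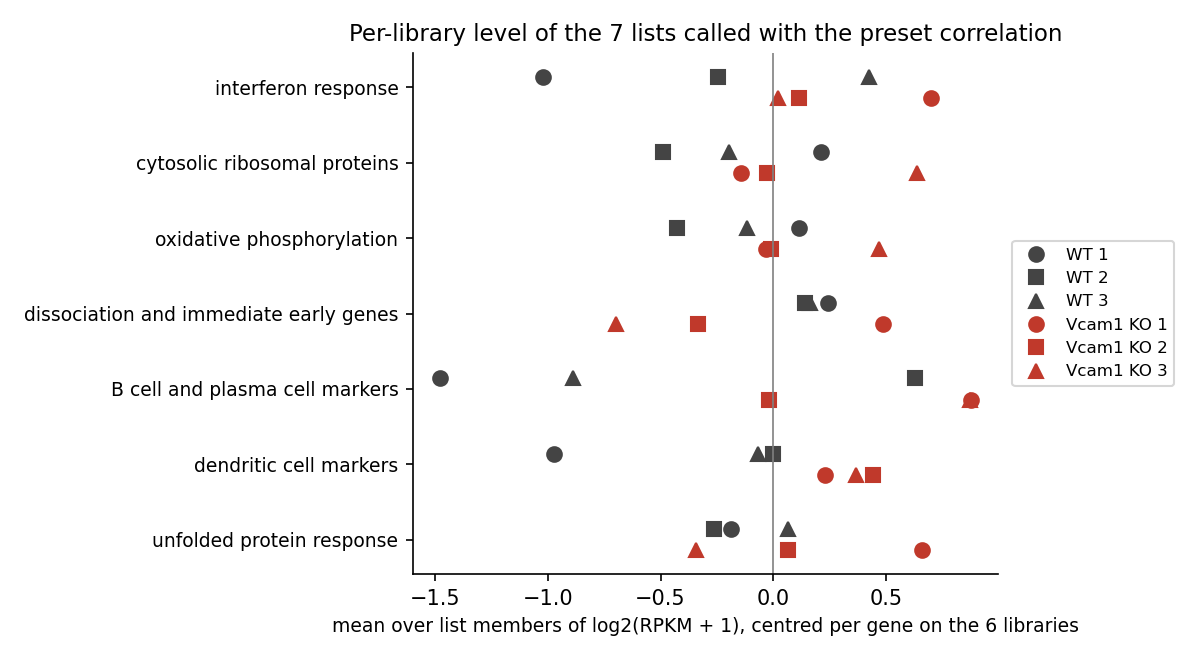
Level of the 7 called lists in each library, as the mean over members of log2(RPKM + 1) centred on the 6 libraries. Grey marks are WT and red marks Vcam1 KO, and the marker shape gives the sample number. WT 1 is lowest for interferon response (-1.02) and Vcam1 KO 3 is highest for cytosolic ribosomal proteins (0.64).

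General macrophage genes were expressed at high levels in both groups. Cd68 averaged 726 ± 162 and 777 ± 34.4 RPKM, Adgre1, which encodes the F4/80 antigen, 384 ± 46.3 and 395 ± 26.6 RPKM, and Csf1r 254 ± 41.8 and 235 ± 30.3 RPKM. The macrophage list was not called (adjusted p = 0.430). Fcgr1, an Fc receptor gene, averaged 93.5 ± 24.1 and 164 ± 29.4 RPKM, and Aif1 averaged 233 ± 59.3 and 353 ± 27.3 RPKM, without passing (adjusted p = 0.970).

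The lists closest to plaque biology were not called. Of foamy macrophage genes, 12 of 24 had a positive log2 fold change (adjusted p = 0.772), with Spp1 called when adjusted over the list alone but not over all genes. Trem2, a lipid receptor gene, averaged 47.5 ± 13 and 50.1 ± 5.40 RPKM. Of efferocytosis genes, which act in the uptake of dying cells, 13 of 24 were positive (adjusted p = 0.772), and the median and mean were above 0 while the test pointed lower. Of cholesterol efflux genes, 9 of 18 were positive (adjusted p = 0.646), with Abca1 at 22.1 ± 3.50 and 25.4 ± 4.08 RPKM and Abcg1 at 54.5 ± 9.07 and 53 ± 3.59 RPKM. Cholesterol synthesis (0.772), lipid uptake (0.329), lysosome and autophagy (0.772) and antioxidant response (0.983) were not called either, by adjusted p.

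Inflammatory, chemokine and adhesion lists were not called. Of inflammatory cytokines and NF-kB targets, 16 of 24 had a negative log2 fold change (adjusted p = 0.0564), with Icam1 at 35.1 ± 7.06 and 22.9 ± 6.73 RPKM and Il1b at 74.6 ± 27.1 and 92.4 ± 30.6 RPKM. The inflammatory list lay near the threshold and was called lower in 7 of 18 alternatives, with adjusted p of 4.0e-05 to 0.0482 in those 7 and up to 0.828 in the others. Of 22 chemokine and chemokine receptor genes, 11 were positive (adjusted p = 0.356), and Ccl12 and Ccl7 were higher when adjusted over the list alone. The chemokine list was called higher in 3 of 18 alternatives (adjusted p of 0.00609 to 0.974 over all 18). Of 19 integrins and adhesion molecules, 10 were negative (adjusted p = 0.221), and Itgb7 and Vcam1 were lower when adjusted over the list alone. Itga4, the alpha chain that pairs with Itgb7, averaged 5.42 ± 0.83 and 5.71 ± 1.07 RPKM. Spp1 and Fn1 were higher in the extracellular matrix list when adjusted over that list alone (list adjusted p = 0.185).

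The remaining lists were not called, with adjusted p of 0.0564 for DNA damage, 0.0629 for alternative activation, 0.136 for nucleic acid sensing, 0.215 for MHC class II, 0.260 for apoptosis, 0.772 for cell cycle, 0.890 for glycolysis and hypoxia, and 0.979 for mitochondrially encoded genes. Of these, DNA damage was called lower and alternative activation higher in 5 of 18 alternatives each, with adjusted p over all 18 of 0.0111 to 0.828 and 0.000279 to 0.828. Markers of other cells were not called either, with adjusted p of 0.185 for smooth muscle and for T and NK cells, 0.221 for red blood cells and platelets and for fibroblasts, 0.400 for monocytes, 0.402 for resident vascular macrophages and 0.734 for adipocytes. Neutrophil, endothelial, mast cell and sex-linked lists had fewer than 3 tested members. Of the fibroblast list, Gsn, which macrophages also express, averaged 63.8 ± 14.3 and 57.7 ± 18.2 RPKM, and Dcn, a proteoglycan gene, 22.4 ± 12.6 and 35.8 ± 32.1 RPKM. Of the neutrophil list Csf3r averaged 13.4 ± 1.80 and 18.2 ± 7.48 RPKM and S100a8 0.069 ± 0.12 and 1.66 ± 1.82 RPKM, and of the endothelial list Pecam1 averaged 3.65 ± 0.96 and 2.78 ± 1.07 RPKM.

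Cd68, Adgre1, Csf1r, Trem2, Abca1, Abcg1, Il1b, Itga4 and Gm44805 were named outside the rule for named genes, after their values were seen. Gm42793 overlaps Spp1 on the same strand, and genes on the opposite strand overlap Csad, Fn1, Ms4a4c, Ptger2, Tnfaip2, Fars2, Csf1r, Icam1, Il1b, Itga4 and Jun, so the levels of these genes are uncertain to that extent.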

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

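Chosen after seeing the data were voom on recovered reads, RPKM scaled to equal sums, and leaving out both libraries with Cd79a transcripts (WT 2 and Vcam1 KO 3) or both with high Chil3 and Cd300e (WT 1 and Vcam1 KO 3). Since the values are RPKM, the alternatives planned for counts (RLE and upper-quartile factors, a Wald test with its own size factors, and voom with sample quality weights) were not run. Lyz1 was called in 15 of 16 alternatives, with adjusted p from 2.2e-05 to 0.110. Fcor was called in 2 of 15 (0.0248 to 0.937, log2 fold change 1.14 to 7.22) and Apoc4 in 2 of 16 (0.0284 to 0.963, log2 fold change -5.84 to -2.02), and the pseudocount and voom set the ends of both fold ranges. Vcam1 stayed lower and uncalled in all 16 (log2 fold change -4.39 to -1.76, adjusted p 0.0741 to 0.999), and so did Lyz2 (-1.23 to -0.54, adjusted p 0.774 to 0.999). For the other 20 named genes, 313 of 314 comparisons kept direction and side of the threshold, and Fn1 was called without WT 2.

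The 3 called genes (2 higher, 1 lower) became 0 (0 and 0) when 24354 genes with any value above 0 were tested, although 717 had an unadjusted p of 0.05 or less. The larger number of tests, and of genes near 0, is part of that setting. With at least 5 RPKM in at least 3 samples, 2 genes were called, 1 higher and 1 lower, and Fcor was not tested. With a pseudocount of 0.1 or 5, with voom, and with either pair of libraries left out, 1 gene was called, 1 higher and 0 lower. Quantile normalization gave 2 higher and 0 lower. Leaving out 1 library gave 1 to 2 genes, 1 to 2 higher and 0 lower. Fewer samples are part of those settings, and otherwise the cause was not tested. With the replicate number as a block, 2 genes were higher (Lyz1 and Cd209a) and 0 lower. Same-numbered samples did not deviate together (correlations of -0.044, -0.019 and -0.058), against -0.011 to 0.062 for other numbers, so nothing in the values pairs the samples by number. Vcam1, Lyz1 and Apoc4 had 1493 to 16816 reads in the WT libraries together, but the Fcor level in WT rests on 1 read.

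List calls depended on the settings, and the cause was not tested unless named. The 7 called lists became 0 with an estimated correlation, where adjusted p was 0.744 for ribosomal proteins, 0.774 for the unfolded protein response and 0.711 for the other 5, and 0 with fry, where it was 0.907 for the unfolded protein response and 0.828 for the other 6. They became 12 without both Cd79a libraries, and 6 to 12 with 1 library left out. By adjusted p, calls ended for dendritic cells without the filter (0.417), for the unfolded protein response with the stricter filter (0.0536) and quantile normalization (0.176), and for B cells with quantile normalization (0.0650). Without both Cd79a libraries, ribosomal proteins (0.0775) and oxidative phosphorylation (0.835) reversed and immediate early genes were not called (0.431). Without both Chil3 libraries, immediate early genes and B cells (0.220 each) and dendritic cells (0.236) were not called. With 1 library left out, adjusted p ranged from 1.0e-22 to 0.164 for interferon response, 3.1e-12 to 0.280 for ribosomal proteins, 5.4e-14 to 0.247 for immediate early genes, 0.000686 to 0.169 for B cells, 0.00302 to 0.421 for dendritic cells and 5.4e-08 to 0.734 for the unfolded protein response. Oxidative phosphorylation was called in each of those 6 fits (6.5e-09 to 0.0464).

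For the 27 lists not called, 384 of 483 comparisons were the same, 40 became calls in the same direction, and 59 reversed, 6 of them as calls. The 40 calls in the same direction were of inflammatory genes in 7 settings (adjusted p 4.0e-05 to 0.0482), alternative activation in 5 (0.000279 to 0.0482), DNA damage in 5 (0.0111 to 0.0388), and nucleic acid sensing, MHC class II and chemokines in 3 each. Extracellular matrix, red blood cell and platelet, fibroblast and lipid uptake had 2 each, and smooth muscle, T and NK, monocyte, resident macrophage, lysosome and mitochondrially encoded 1 each. Reversed, by adjusted p, were adipocyte (0.954) and cholesterol synthesis (0.723) without the filter, cell cycle (0.730), cholesterol synthesis (0.714) and antioxidant (0.779) with the stricter filter, and mitochondrially encoded and antioxidant with a pseudocount of 5 (0.991 each). With quantile normalization these were chemokines and cholesterol synthesis (0.937 each), macrophage (0.184), foamy (0.541), glycolysis (0.580) and antioxidant (0.576), with the block antioxidant (0.967), with equal sums glycolysis (0.935) and antioxidant (0.979), and with fry efferocytosis (0.997) and mitochondrially encoded (0.974). Without both Cd79a libraries they were monocyte (0.209), macrophage (0.543), cholesterol efflux and synthesis (0.820 each), foamy (0.0211), glycolysis (0.995), mitochondrially encoded (0.0177) and antioxidant (0.128). Without both Chil3 libraries they were T and NK (0.892), lipid uptake and adipocyte (0.692 each), resident macrophage (0.00902), lysosome and efferocytosis (0.236 each) and cell cycle (6.6e-11). With 1 library left out, ranges that include a reversal were 0.0124 to 0.669 for MHC class II, 0.0484 to 0.682 for lipid uptake, 0.0535 to 0.983 for resident macrophage, 0.0294 to 0.984 for lysosome, 0.00101 to 0.429 for cell cycle, 0.108 to 0.983 for efferocytosis, 0.159 to 0.679 for macrophage, 0.0868 to 0.969 for foamy, 0.461 to 0.893 for cholesterol synthesis, 0.358 to 0.870 for glycolysis, 0.00903 to 0.743 for mitochondrially encoded, 0.194 to 0.752 for antioxidant, 0.0124 to 0.860 for chemokines, 0.0568 to 0.984 for adipocyte and 0.0207 to 0.885 for monocyte genes.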

Other observations

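Transcripts of other cells and states differed between libraries of the same group. Several monocyte genes were high in WT 1 and Vcam1 KO 3. Chil3 was at 215 and 33.0 RPKM in these libraries and at 0 to 1.57 RPKM in the other 4, Cd300e at 42.8 and 25.3 RPKM against 0.010 to 4.39, and Treml4 at 41.6 and 30.4 RPKM against 1.06 to 2.91. Ccr2, a chemokine receptor gene of the same list, went another way, at 57.6 and 65.3 RPKM in these libraries and at 99.6 RPKM in WT 2, 49.2 in WT 3, and 109 and 155 in Vcam1 KO 1 and 2. Cd79a, a B cell receptor gene, was at 13.2 RPKM in WT 2 and 22.4 RPKM in Vcam1 KO 3, and at 0 to 0.050 RPKM elsewhere. Jchain, a plasma cell gene, was at 37.1 RPKM in Vcam1 KO 1, where Cd79a was listed at 0, and at most 2.78 RPKM in the other 5. Mzb1, of the same fixed list as Jchain, was at 0.77 RPKM in Vcam1 KO 1 and at 33.3 RPKM in Vcam1 KO 3, where Jchain was at 0.42 RPKM. Nkg7, a gene of cytotoxic lymphocytes, was at 18.0 RPKM in Vcam1 KO 3, 4.0 RPKM in Vcam1 KO 1 and 0 in the other 4. Mki67, a gene of dividing cells, was at 1.29, 8.41 and 7.68 RPKM in WT 1 to 3, and at 2.64, 3.24 and 6.44 RPKM in Vcam1 KO 1 to 3. Cd79a, Cd300e, Treml4, Jchain, Mzb1 and Mki67 were named after their values were seen.

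Csad and Itgb7 lie close together on chromosome 15 (102176999 to 102204724 and 102215995 to 102231944) and differed in opposite directions, with log2 fold changes of 1.39 and -1.84, neither past the adjusted threshold (0.785 and 0.514). Xist, which Tsix overlaps on the opposite strand, was at 7.41 to 13 RPKM in all 6 libraries, and the Y-linked genes had few reads or none. Ddx3y and Uty had 0 in all 6, Eif2s3y had 1 each in Vcam1 KO 2 and 3, and Kdm5d had 1 in WT 3, 1 in Vcam1 KO 2 and 2 in Vcam1 KO 3.

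Tests chosen after their result was seen were those of Lyz1 and Lyz2 and the use of the fits without WT 1, Vcam1 KO 3 or WT 2 alone as tests of list calls, although leaving out each sample was itself planned.

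Lyz1 was 27.4 times higher in Vcam1 KO while Lyz2 was lower, on neighbouring positions of chromosome 10. Lyz2 reads counted on Lyz1 at a fixed share would keep the Lyz1 percent of Lyz2 in 1 range, yet the lowest Vcam1 KO percent was 34.0 times the highest WT percent. That argues against a share that was the same in both groups. A share that differed between the groups was not tested. A lower Lyz2 may reflect 1 copy replaced by Cre, as its log2 fold change of -0.86 has a 95% interval of -1.71 to -0.02 that includes a halved level. The WT mean leaned on WT 1, at 20192 RPKM against 9029 and 11463 RPKM in WT 2 and 3. Without WT 1 the log2 fold change of Lyz2 was -0.54. DNA of another strain linked to the Cre allele stays open, because within 5 Mb 2 of 29 other genes (Mdm1 and Nup107, 6.90%, exact 95% interval 0.846 to 22.8%) had an unadjusted p of 0.05 or less against 4.19% elsewhere (one-sided Fisher's exact p = 0.345), too few to decide. Cre is present in all Vcam1 KO and no WT samples, so an effect of the Cre allele and an effect of VCAM-1 loss cannot be separated for Lyz1 or for any other result, and neither was tested.

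Interferon response genes were called higher in Vcam1 KO as a list with the preset correlation, but not with an estimated correlation (adjusted p = 0.711) or by fry (adjusted p = 0.828). Without WT 2 and Vcam1 KO 3, where Cd79a was seen, the list was still called higher (camera with the preset correlation, adjusted p = 6.6e-10). Its median log2 fold change was then 0.67, which argues against these 2 libraries as the whole source. The call itself cannot exclude B cells, since with the preset correlation 7 or more lists were called in 9 of 10 splits of the samples. That fit also kept Vcam1 KO 1, which had the highest level of both the B cell and plasma cell list (0.88) and the interferon list (0.70). B-lineage cells there stay open. A trend with gene length and mean level, removed together, is argued against as the whole source, with the median moving from 0.57 to 0.43. The median length of the list was 3545 bases against 3596 for all genes, so a length trend had little to shift. With the preset correlation the list was still called after that removal (camera, adjusted p = 1.6e-07). As above, that call itself cannot exclude such a trend. The single library WT 1 may account for the call, because without it the adjusted p was 0.164 and the median fell from 0.57 (SD over members 0.41) to 0.27 (SD 0.41), with 26 of 38 members positive. The call ended with that smaller median and 1 sample fewer, and an effect of VCAM-1 loss or of the Cre allele on these genes stays open.

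Ribosomal protein and oxidative phosphorylation genes were called higher in Vcam1 KO with the preset correlation, but not with an estimated correlation (adjusted p = 0.744 and 0.711) or by fry (0.828 for both). Both lists hold short genes, with a median recovered gene length of 1692.5 and 1774.5 bases against 3596 for all genes. That length covers all exons of a gene where it matched the annotation, and is not the length of 1 transcript. Within libraries, the deviation of a gene from its mean went with gene length in opposite ways in WT 2 and Vcam1 KO 3 (Spearman's rho across genes, which are not independent, of 0.24 and -0.24). A trend on gene length and mean level together was then removed in each library. The medians fell from 0.30 (SD 0.095) to 0.11 (SD 0.11) and from 0.29 (SD 0.16) to 0.11 (SD 0.15). The larger adjusted p by camera was 0.0518 for oxidative phosphorylation, against 0.0296 for ribosomal proteins. Length and level together may account for most of the difference, but length alone was not tested. Without Vcam1 KO 3 the ribosomal protein list was not called (camera, adjusted p = 0.280, median 0.07), so that library alone may account for that call. Oxidative phosphorylation was still called without it (adjusted p = 0.0464, median 0.12, 36 of 44 members positive). Without WT 2 both lists were still called (larger adjusted p = 0.0322), with medians of 0.15 and 0.14. The calls that stayed cannot exclude either library as the whole source, since with the preset correlation 7 or more lists were called in 9 of 10 splits of the samples. Without both libraries the medians were -0.11 and -0.013, with 8 of 48 and 20 of 44 members positive, so both differences went with these 2 libraries. An effect of VCAM-1 loss or of the Cre allele stays open.

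The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. As many as 3 changed genes came from 2 of the 10 splits, with a highest value of 3 among the others, for the split that sets WT 1, WT 2 and Vcam1 KO 3 against the rest. As many as 2 genes in 1 direction also came from 2 of 10 splits (highest other 3), and 1 gene in the opposite direction from 1 of 10 (highest other 0). As many as 7 lists were called in 9 of 10 splits, and the highest other value was 16. The correlation estimated within 5 of the 7 called lists was 0.51 to 0.93, far above the preset 0.01, and whether that or a structure of the samples gave calls in other splits was not tested.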
